A study of Homo sapiens with 8 samples.

How the data were processed

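Total RNA of 8 human anterior cruciate ligament samples was extracted with TRIzol and purified on columns, per the labels' protocols. Libraries were made from 10 ng of total RNA after DNase treatment, amplified to double-stranded cDNA with the SeqPlex RNA kit and then by 12 cycles of PCR. They were sequenced on an Illumina HiSeq instrument as single reads of 50 bases with a target of 30M reads per sample. Whole-transcriptome amplification from little RNA, PCR duplicates without molecular identifiers and short unpaired reads can distort levels, and short reads divide poorly between near-identical genes. CASAVA 1.8.2, STAR 2.0.4b, Subread, featureCounts 1.4.5 and the genome build GRCh38 are named per the submitters' processing notes, without their roles. The strand setting, the handling of reads that map to several places and the Ensembl release are not given in the sources used here. Where antisense or overlapping genes share a locus, their reads may not be told apart.

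Each deposited file lists 62757 Ensembl features with whole-number read counts, per the file headers. The authors also deposited CPM, which equals the count divided by the library's summed counts per 1000000, and RPKM, which divides that CPM by the feature's length in kilobases. All tests started from the deposited counts, and the CPM and RPKM columns served to check the columns against each other. Summed counts per library were between 7450515 and 13971780 (median 10949397.5). Of the features, 54837 had a symbol in the name table used and 55298 had one from it or from GENCODE 29. The files include 3945 features on alternate loci of the assembly.

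Gene lists, tests, thresholds, list pairs and the alternatives listed here were fixed before the data were examined. Exceptions are named as chosen later or as departing from the plan. Counts were scaled with edgeR 4.0.16 by trimmed mean of M values (factors 0.873 to 1.17) in R 4.3.3, on features with a total of at least 80 counts, and log2 CPM used a prior count of 2. Gene levels are given as counts per 1000000 of the library total multiplied by its factor, and shares of counts are relative to the total itself. Differences beyond counting error were tested per feature by a chi-square test of homogeneity of the 8 counts (7 degrees of freedom) with Benjamini-Hochberg adjustment at 0.05. The same test on pairs of libraries looked for a library present more than 1 time. These are tests of counting error, not of groups.

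The spread of a list is the median over its members of the interquartile range of log2 CPM, and its shared movement is the mean Pearson correlation over pairs of members. Members needed a median of at least 1 CPM, with at least 3 members for spread and 4 for shared movement. Each value was set against 10000 random lists of the same size, matched on mean log2 CPM in 20 bins from 15133 genes. The test was two-sided for spread and one-sided for shared movement, with Benjamini-Hochberg adjustment over the lists. The 33 lists held 376 symbols found in the files, and FCGR3B was not used. A list score is the mean log2 CPM of its members. Scores were correlated for 20 pairs of lists, and with 3 technical measures in 93 pairs, by exact permutation over all pairings of the libraries. Where a list's scores fell into separate clusters, with a gap of over 0.5 of their range and at least 2 libraries on each side, only a cluster of at least 6 libraries was used. The plan gave no correlation for such lists, so this use of a cluster departs from the plan. Principal components used the 500 most variable genes.

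Genes are named by a fixed rule. In each list these are the 3 members with the highest median CPM and the 3 with the widest interquartile range. To these come the 10 genes with the highest median CPM, the 10 with the highest length-scaled value, and, at a median of at least 5 CPM, the 20 widest and the 10 narrowest. The rule also held the 10 genes with the widest gap between the highest library and the next. That part was dropped after the data were seen, because most of its members were pseudogenes that share reads with mitochondrial or ribosomal protein genes and could describe 1 person. Y-linked genes, XIST, classical HLA genes, variable segments of antigen receptors and commonly deleted genes were left out by plan, and X-linked genes with a Y-linked partner were left out after the data were seen (1218 features in all). FMOD, COMP, COL12A1, genes listed at a count of 0 and genes inside the spans of alternate loci were named after their values were seen. Some genes that the rule names are not reported here.

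The alternatives were DESeq2 1.42.0 size factors, plain CPM, totals without mitochondrial and ribosomal RNA genes, thinning to the smallest library, other detection and member minimums, a prior count of 0.5, no filter on low counts, a doubled Poisson variance, range instead of interquartile range, Spearman correlation, other list scores and leaving out each library in turn. Leaving out libraries 7 and 8 together was chosen after seeing the data. Statistics used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

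The code was tested on simulated data. Among 15954 simulated features with 200 changed, the test of counting error called 0.0449% of unchanged features, 62.7% of those changed 1.5-fold, 86.6% at 2-fold and 100% at 4-fold. The list tests found 20 of 20 lists with shared movement and 17 of 20 wide lists, and each test called 1 of 110 null lists. The correlation test called 4.33% of 300 independent pairs and 99% of 300 pairs simulated with a correlation of 0.95. These pairs used all 8 libraries and unadjusted p, so the cluster rule and the adjustment were not tested. Outside the planted lists the simulated genes varied independently, and unchanged features varied by Poisson sampling alone. Error rates where many genes move together were therefore not measured.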

Results

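RNA from torn human anterior cruciate ligament was measured by RNA sequencing. This ligament joins the femur to the tibia inside the knee and restrains forward sliding of the tibia. The series was designed to relate transcript levels to the time since injury. The labels used here give the tissue of each of the 8 libraries but no time since injury and no other group. All 8 were therefore left unassigned, each is reported by its own value or by the median and range, and no comparison between groups was made. The libraries are numbered 1 to 8 in the order of their records, which the labels tie to no time or batch. Each carries its own sample code, but the labels do not state whether they came from separate donors, so the spread among them may be technical.

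The ligament libraries were rich in mitochondrial transcripts and, except for libraries 7 and 8, in collagen transcripts. Genes for collagens, the fibre-forming proteins of ligament, took a median of 9.21% of gene counts, with a range from 1.11% in library 8 (95% Wilson interval 1.11% to 1.12%) to 17.4% in library 3 (17.36% to 17.41%). Their shares were 16.1% in library 1, 8.86% in library 2, 16.6% in library 4, 8.94% in library 5, 9.48% in library 6 and 1.62% in library 7. Mitochondrial transcripts, which encode respiratory chain subunits and the organelle's ribosomal RNAs, took a median of 25.6%, from 18.9% in library 4 to 43.4% in library 8. Total gene counts were 10140296, 13891205, 7450515, 8737379, 7453494, 11758499, 13971780 and 12169733 in libraries 1 to 8. A floor of 3 counts corresponded to between 0.183 and 0.419 counts per 1000000 (CPM). Intervals and floors cover counting error only. They do not allow for PCR duplicates, which could not be told apart because the reads carried no molecular identifiers.

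**Figure D1:**
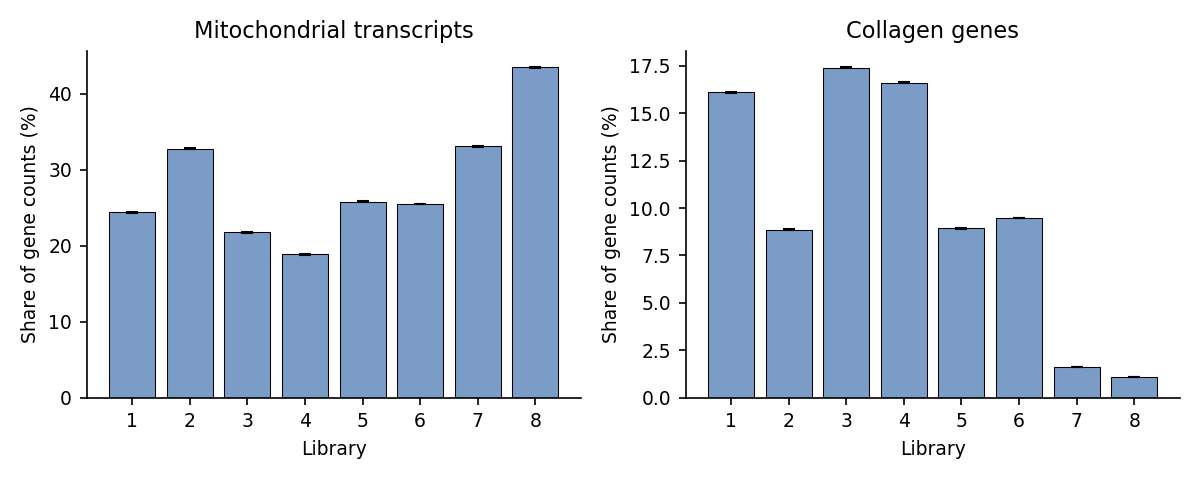
Share of gene counts (%) from mitochondrial transcripts (left) and collagen genes (right) in each of the 8 libraries, with bars for single libraries and error bars for 95% Wilson intervals, which cover counting error only. The collagen share ran from 1.11% to 17.4% and the mitochondrial share from 18.9% to 43.4%.

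The nuclear gene with the highest median was FN1, which encodes the matrix glycoprotein fibronectin, at 57173 CPM (range 32025 to 102064). COL1A1 and COL1A2, the chains of type I collagen, had medians of 37366 and 13723 CPM, and COL3A1, the chain of type III collagen, had 29189 CPM. MALAT1, a nuclear long noncoding RNA, had a median of 12054 CPM (8131 to 13891). The other members of the 10 most abundant genes were mitochondrial. MT-RNR2 and MT-RNR1, the mitochondrial ribosomal RNAs, had medians of 99474 and 76655 CPM. MT-ND4 and MT-ND5, subunits of complex I, had 19216 and 8453 CPM, and MT-CO1, a subunit of cytochrome c oxidase, had 8904 CPM. After scaling by gene length, the 10 highest genes were MT-RNR1, MT-RNR2, MT-ND4L, MT-ND4, the small nuclear RNA 7SK, MT-ATP6, MT-CO3, MT-CO2, MT-CO1 and MT-CYB. Nuclear copies of mitochondrial sequence share reads with these genes, so their levels are uncertain. On GRCh38 the files place COL1A1 on chromosome 17 from 50183289 to 50201632, FN1 on chromosome 2 from 215360440 to 215436172 and COL3A1 on chromosome 2 from 188974320 to 189012746.

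Of 62757 annotated features, 12584 reached 1 CPM in every library, and 11340 of these were protein-coding. At least 1 library reached this level for 18597 features. Single libraries held between 14677 and 16065 such features (median 15232). Of 15954 features with at least 80 counts in all, 13715 differed among the libraries by more than counting error (chi-square test of homogeneity, 7 degrees of freedom, Benjamini-Hochberg adjusted), and the median chi-square per degree of freedom was 7.20. All 307 members of the gene lists that had enough counts were among them. In pairs of libraries the median chi-square per gene was between 1.72 and 7.86, so no pair differed by as little as sampling noise.

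Fibrillar collagens had a wider spread across libraries than the crosslinking, small leucine-rich proteoglycan, other ligament matrix, and tendon and ligament cell lists. The myofibroblast and cartilage lists were wider still (1.46 and 1.49). COL1A1 ranged from 1572 CPM in library 7 to 73060 CPM in library 4, a 46.5-fold range. COL1A2 ranged from 1718 to 23847 CPM and COL3A1 from 3249 to 68288 CPM. The median interquartile range of the 10 collagen genes and partners was 1.41 on the log2 scale, against 0.38 for random lists of like expression (adjusted p = 0.000477). Their levels moved together across libraries, with a mean pairwise correlation of 0.67 (adjusted p = 0.000375). Genes that modify and crosslink collagen also varied together, with a spread of 1.07 and a mean correlation of 0.66. LOXL2, a lysyl oxidase that crosslinks collagen, had a median of 237 CPM (19.5 to 550), and SERPINH1, the collagen chaperone, had 236 CPM (39.0 to 296). PLOD1 and PLOD2, lysyl hydroxylases of collagen, had medians of 234 and 126 CPM, and P4HA1, a prolyl hydroxylase subunit, had 69.6 CPM.

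Small leucine-rich proteoglycans, which bind collagen fibrils and set their diameter, had varied levels. DCN (decorin) had a median of 1257 CPM (997 to 3036), BGN (biglycan) 4509 CPM (1460 to 5815) and ASPN (asporin) 1468 CPM (320 to 2524). PRELP and OGN, further members of the family, had medians of 456 and 150 CPM. The list was wider than random lists (0.89 against 0.37, adjusted p = 0.0106) but its 9 members did not move together (mean correlation 0.12, adjusted p = 0.270). Without library 5 the spread of this list no longer passed the threshold (adjusted p = 0.0994), nor did it without libraries 7 and 8, a choice made after seeing the data (adjusted p = 0.130). The 14 other ligament matrix proteins gave nearly the same mean level in every library, from 8.11 to 8.45 log2 CPM, although single members varied. SPARC, a collagen-binding glycoprotein, had a median of 6511 CPM (1438 to 10220), TNC (tenascin C) 2517 CPM (475 to 3170) and MFAP5, a microfibril protein, 28.2 CPM (8.94 to 245). Their spread was wide (0.81, adjusted p = 0.000827) and their mean correlation was -0.06.

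Tendon and ligament cell genes were led by THBS4, a thrombospondin of tendon matrix, at a median of 198 CPM (141 to 832). DPT (dermatopontin) had 129 CPM and CLEC3B (tetranectin) had 39.7 CPM. ANGPTL7, a secreted angiopoietin-like protein, ran from 1.43 to 202 CPM, and the transcription factor EGR2 from 4.04 to 83.2 CPM. FGF18, a growth factor of skeletal tissue, had a median of 2.20 CPM. The list was wide (1.23, adjusted p = 0.00276) without shared movement (mean correlation -0.07).

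**Figure D2:**
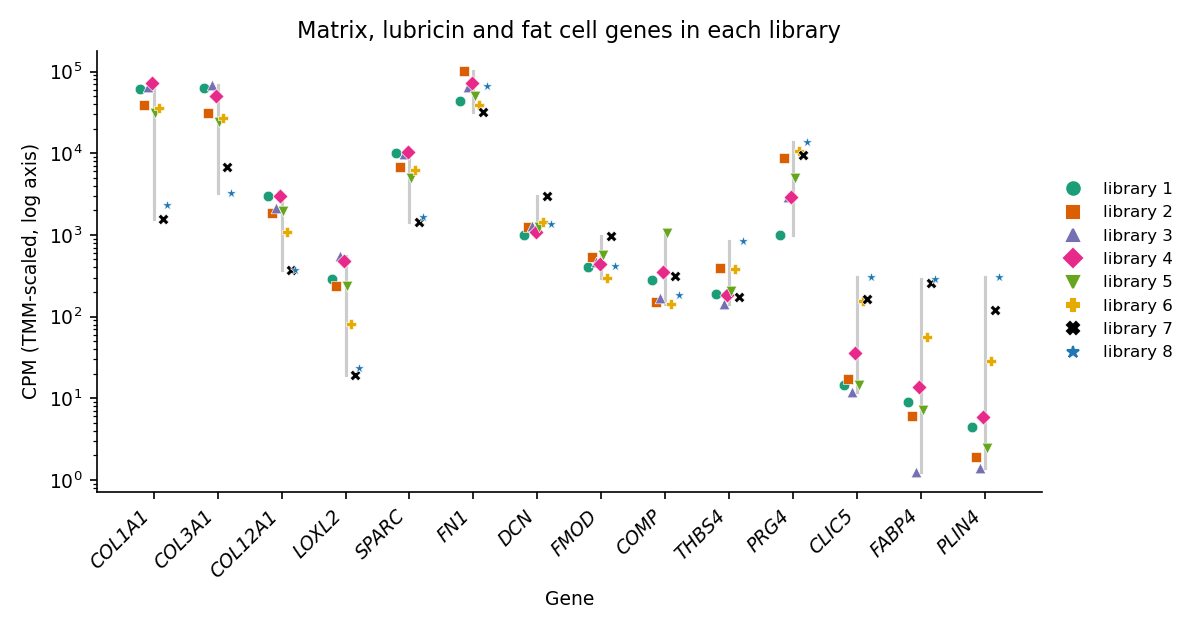
Normalised CPM on a log axis for 14 genes of matrix, joint lubrication and fat cells, with each library as its own symbol and a grey line from the lowest to the highest library. COL1A1 ran from 1572 to 73060 CPM, while DCN stayed between 997 and 3036 CPM. COL12A1, FMOD and COMP were added after their values were seen.

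Genes for enzymes that break down matrix included some of the most variable ones. MMP9, a gelatinase, had a median of 28.2 CPM and ran from 0.061 CPM (1 count) to 166 CPM. MMP13 and MMP1, collagenases, had medians of 63.9 CPM (1.10 to 264) and 14.6 CPM (0.305 to 55.0). MMP2, the other gelatinase, had a median of 2312 CPM (341 to 4858), MMP14, a membrane-bound protease that activates MMP2, had 504 CPM, and ADAMTS2, which trims procollagen, had 471 CPM. The 13 proteases used had a spread of 1.37 (adjusted p = 0.000477) and a mean correlation of 0.60 (adjusted p = 0.000250). Without libraries 7 and 8, a choice made after seeing the data, the shared movement of the proteases no longer passed the threshold (adjusted p = 0.150). Inhibitors of these enzymes did not move together (mean correlation -0.09), although they varied (spread 1.01). TIMP2 ranged only from 1790 to 2776 CPM, TIMP3 from 321 to 1916 CPM and the protease trap A2M from 175 to 924 CPM. SERPINE2, a serine protease inhibitor, had a median of 80.2 CPM (12.0 to 217).

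Myofibroblast and wound contraction genes were led by POSTN (periostin, a matrix protein of healing tissue) at a median of 1049 CPM (43.2 to 3278). ADAM12, a metalloprotease of activated fibroblasts, had 499 CPM (6.04 to 922), LRRC15, a membrane protein of such cells, 393 CPM (38.3 to 504) and LRRC17 42.7 CPM. The list was wide (1.46, adjusted p = 0.000477) and its members did not move together as a group (mean correlation 0.14, adjusted p = 0.141). Growth factors of repair had a spread of 0.91 (adjusted p = 0.000477) and a mean correlation of -0.01. Among them CCN2, a matricellular growth factor, had a median of 226 CPM (141 to 407), TGFB3 185 CPM (72.2 to 309) and VEGFA, the main growth factor of vessels, 172 CPM (28.9 to 413). BMP6 and FGF2 had medians of 13.2 and 1.72 CPM. Genes of the hypoxia response varied together (spread 1.15, mean correlation 0.60), with NDRG1 at 314 CPM, the glycolytic genes LDHA and ENO2 at 228 and 76.2 CPM, ANGPTL4 at 14.6 CPM and the oxygen sensor EGLN3 at 8.66 CPM.

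Cartilage and bone genes were present at lower levels. Of 15 cartilage genes 6, and of 9 bone genes 4, reached a median of 1 CPM. ACAN, the large proteoglycan of cartilage, had a median of 99.4 CPM (4.76 to 247), COL11A1, a cartilage collagen, 41.5 CPM (0.732 to 181) and the chondrocyte regulator SOX9 12.6 CPM, while CHAD, a cartilage matrix protein, had 1.70 CPM. The 6 cartilage members used were wide (1.49, adjusted p = 0.000827) with a mean correlation of 0.27 (adjusted p = 0.0436). The spread of the cartilage list was lost without library 6 (adjusted p = 0.114), and its shared movement without library 5 (adjusted p = 0.0613), under plain CPM (adjusted p = 0.121) and with members of any count (adjusted p = 0.168). RUNX2, a regulator of osteoblasts, had a median of 96.6 CPM, ALPL, the bone alkaline phosphatase, 28.6 CPM and IBSP, bone sialoprotein, 3.0 CPM. In libraries 7 and 8 IBSP had only 2 and 3 counts. The bone list passed both thresholds (spread 1.06, adjusted p = 0.0369; mean correlation 0.43, adjusted p = 0.0366), and it lost both under plain CPM (adjusted p = 0.0774 and 0.121), without library 8 (adjusted p = 0.289 and 0.0526), with members of any count (adjusted p = 0.145 and 0.448) and without libraries 7 and 8, chosen after seeing the data (adjusted p = 0.663 and 0.318). It also lost spread with a prior count of 0.5 (adjusted p = 0.0536) and without library 7 (adjusted p = 0.217), and shared movement after thinning (adjusted p = 0.0723) and without library 1 or 2 (adjusted p = 0.0510 and 0.0614). Of the osteoclast list only CTSK (cathepsin K, 153 CPM) and ACP5 (tartrate-resistant phosphatase, 10.4 CPM) reached a median of 1 CPM, too few for a test.

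Inflammatory cytokines and chemokines were low but variable. CXCL12, a chemokine of stromal cells, had a median of 121 CPM (25.3 to 408), the cytokine LIF 19.7 CPM (1.77 to 49.4) and the monocyte attractant CCL2 17.4 CPM (9.22 to 58.9). The neutrophil attractants CXCL8 and CXCL2 had medians of 1.73 and 4.11 CPM and IL1B, a cytokine of activated macrophages, 2.01 CPM. The list of 8 used members had a spread of 1.89 against 0.49 for random lists and a mean correlation of 0.50. Its shared movement was lost when only members with a median of at least 5 CPM were kept (adjusted p = 0.152).

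Among immune cell lists, macrophage genes were the most abundant. C1QC, a complement subunit made by macrophages, had a median of 204 CPM (107 to 238), CSF1R, the macrophage growth factor receptor, 191 CPM (150 to 258) and the scavenger receptor CD163 88.2 CPM (41.1 to 177). VSIG4 and MARCO, receptors of tissue macrophages, had 45.8 and 26.6 CPM. The spread of the macrophage list was 0.52, not past the threshold (adjusted p = 0.0612), while its members moved together (mean correlation 0.55, adjusted p = 0.000375). The macrophage spread passed under plain CPM (adjusted p = 0.0228), without mitochondrial and ribosomal RNA genes (adjusted p = 0.0456), without library 2, 4 or 8 (adjusted p = 0.0367, 0.0351 and 0.00465) and without libraries 7 and 8, chosen after seeing the data (adjusted p = 0.00590). T and natural killer cell genes were low, with TRAC, the constant part of the T cell receptor alpha chain, at 6.78 CPM, IL7R at 3.43, PRF1 (perforin) at 2.13 and CD2 at 1.54 CPM. They moved together (mean correlation 0.76) with a spread of 0.90, not past the threshold (adjusted p = 0.192). This spread passed in 5 of 15 other settings: without mitochondrial and ribosomal RNA genes (adjusted p = 0.0117), with members of any count (adjusted p = 0.00440), by range (adjusted p = 0.0448) and without library 6 or 8 (adjusted p = 0.0178 and 0.0171). Of B and plasma cell genes, CD79B alone reached a median of 1 CPM (1.01 CPM), so the list was not tested. Neutrophil genes included CSF3R at 17.2 CPM, S100A8 at 10.5, FPR1 at 7.26 and S100A9 at 2.08 CPM, with a spread of 0.88 (adjusted p = 0.0902) and a mean correlation of 0.77. The neutrophil spread passed with members of any count (adjusted p = 0.0215), by range (adjusted p = 0.00904) and without libraries 7 and 8 (adjusted p = 0.0480). Mast cell genes had the widest spread of all lists (3.28 against 0.56 for random lists) and a mean correlation of 0.75. TPSAB1, a tryptase of mast cell granules, ran from 0.0825 CPM (1 count) to 25.3 CPM, and CPA3, their carboxypeptidase, from 0.165 to 24.7 CPM. KIT, the stem cell factor receptor, had a median of 11.5 CPM. TPSAB1 and TPSB2 (median 2.99 CPM) are near-identical copies, so the division of reads between them is uncertain.

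Endothelial genes moved together almost completely, with a mean correlation of 0.91 over 12 members. PECAM1, a junction protein of vessel lining, had a median of 546 CPM (166 to 745), VWF, the von Willebrand factor, 212 CPM (30.5 to 464) and the transcription factor ERG 82.2 CPM (24 to 109). EMCN (endomucin) and the angiopoietin receptor TEK had medians of 33.3 and 11.8 CPM. The endothelial spread was 1.06 (adjusted p = 0.000477). Lymphatic vessel genes were wide (1.57, adjusted p = 0.00255) with a mean correlation of 0.35 (adjusted p = 0.0366). Shared movement of the lymphatic list was lost under plain CPM (adjusted p = 0.0780), without library 2 (adjusted p = 0.0688) and without library 3 (adjusted p = 0.188). LYVE1, a hyaluronan receptor also found on macrophages, had a median of 80.5 CPM, MMRN1 15.3 CPM, FLT4 10.8 CPM and the chemokine CCL21 2.13 CPM. Pericyte and vascular smooth muscle genes varied (0.92, adjusted p = 0.00620) without moving together (mean correlation 0.05). PDGFRB, a receptor of mural cells and fibroblasts, was nearly even at 262 to 475 CPM, NOTCH3 had a median of 286 CPM and MCAM 184 CPM. RGS5, NDUFA4L2 and DES had medians of 177, 61.9 and 12.1 CPM.

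Fat cell genes had the widest range of list scores. Their mean level was 2.56, 1.74, 0.52, 2.30, 1.36, 3.59, 5.82 and 7.33 log2 CPM in libraries 1 to 8. In library 3 the level is limited by few counts, with 1 for ADIPOQ, 4 for PLIN1 and 9 for FABP4. FABP4, a fatty acid carrier, ran from 1.26 to 287 CPM, PLIN4 and PLIN1, coat proteins of lipid droplets, from 1.4 to 304 and from 0.559 to 240 CPM, and the hormone ADIPOQ from 0.140 to 93.2 CPM. LPL (lipoprotein lipase) and GPAM, an enzyme of triglyceride synthesis, had medians of 15.2 and 14.4 CPM. The list had a spread of 2.59 and a mean correlation of 0.90. Synovial lining genes were led by PRG4 (lubricin, the lubricant of joint surfaces) at a median of 6762 CPM (993 to 13774), followed by CD55 at 133 CPM and the integrin subunit ITGB8 at 104 CPM. CLIC5, a protein of the cell cortex, ran from 12.0 to 305 CPM, HBEGF, a ligand of the EGF receptor, from 9.54 to 168 CPM and the defensin DEFB1 from 0.408 to 5.31 CPM. The synovial list had a spread of 1.73 and a mean correlation of 0.60. Their scores were 4.57, 5.75, 4.60, 5.66, 4.51, 6.68, 6.18 and 6.71 in libraries 1 to 8.

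Of 12 skeletal muscle genes, 4 reached a median of 1 CPM. TTN (titin) had a median of 101 CPM, NEB (nebulin) 15.1, and the fast-fibre troponins TNNT3 and TNNC2 had 3.12 and 1.4 CPM. These values are not scaled by gene length, so they do not rank the genes by transcript number. Neither the spread (0.92, adjusted p = 0.0866) nor the mean correlation (0.12) of the muscle list passed the threshold. Of 9 red cell genes, 3 reached a median of 1 CPM. These differed widely (1.72, adjusted p = 0.0116), with HBB, the beta chain of hemoglobin, at 6.63 to 126 CPM. HBA2 and HBA1, the near-identical alpha chain genes, had medians of 7.60 and 3.62 CPM and an uncertain division of reads. The red cell spread was lost without library 1 (adjusted p = 0.0835), without library 2 (adjusted p = 0.0922) and with members of any count (adjusted p = 0.185). Of Schwann cell and nerve genes, the myelin protein gene MBP had a median of 23 CPM, NCAM1 14.6 and S100B 1.27 CPM. Their spread was 1.46 (adjusted p = 0.00294) and their mean correlation 0.35 (adjusted p = 0.00967), and neither passed without libraries 7 and 8 (adjusted p = 0.419 and 0.686), a choice made after seeing the data.

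Cell cycle genes moved together closely, with a mean correlation of 0.91 over 14 members. MKI67, a marker of dividing cells, had a median of 66 CPM (4.63 to 207), TOP2A, a topoisomerase of replicating cells, 16.2 CPM (1.46 to 59.9), the centromere protein CENPF 15.4 CPM and BIRC5 (survivin) 4.88 CPM. Their spread was 2.14. Immediate-early genes, transcribed within minutes of a stimulus, were high and varied together (spread 1.49, mean correlation 0.79). EGR1, a zinc-finger transcription factor, had a median of 724 CPM (355 to 3932), FOSB 403 CPM (106 to 2413), KLF6 317 CPM, the nuclear receptor NR4A1 28.8 CPM (9.30 to 323) and ATF3 10.5 CPM. Heat shock proteins, chaperones of stressed cells, were nearly even as a list, although single members varied. The list used 8 of 11 genes, without HSPA1A and HSPA1B, which were listed at a count of 0 and are uncertain. The mean level of the genes used was between 5.60 and 5.95 log2 CPM in all 8 libraries. Neither their spread (0.42, adjusted p = 0.496) nor their mean correlation (0.02) stood apart from random lists. HSP90AA1 had a median of 402 CPM, DNAJB1 141 (63.9 to 182), HSPB1 51.2, HSPH1 47.8 (18.7 to 78.6), CRYAB 47.3 (38.2 to 201) and HSPE1 13.9 CPM. The 2 highest values of CRYAB, 201 and 165 CPM, were in libraries 7 and 8.

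Interferon response genes moved together (mean correlation 0.57) with a spread of 0.53 (adjusted p = 0.103). Their spread passed by range (adjusted p = 0.00124), without library 2, 6, 7 or 8 (adjusted p = 0.0253, 0.0315, 0.0110 and 0.0146) and without libraries 7 and 8, a choice made after seeing the data (adjusted p = 0.00261). IFI6, an interferon-induced protein, had a median of 130 CPM, the antiviral enzyme OAS3 74.7, IFI44L 23.6, IFIT3 17.7 and IFIT1 9.79 CPM. Mitochondrial messenger RNAs also moved together (mean correlation 0.81) with a spread of 0.60 (adjusted p = 0.0841). That spread passed with members of any count (adjusted p = 0.0225), by range (adjusted p = 0.0464) and without library 1, 5, 6, 7 or 8 (adjusted p = 0.0378, 0.0286, 0.0313, 0.0129 and 0.0451). Complex I genes MT-ND2, MT-ND1 and MT-ND6 had medians of 2958, 2813 and 1178 CPM. Housekeeping references had the narrowest spread of the lists tested (0.40, adjusted p = 0.584). Their mean correlation was 0.29 (adjusted p = 0.00865), which did not pass without libraries 7 and 8 (adjusted p = 0.400). ACTB (beta-actin) had a median of 2367 CPM, the glycolytic gene GAPDH 942 (275 to 1479) and TFRC, the transferrin receptor, 22.9 CPM.

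**Figure D3:**
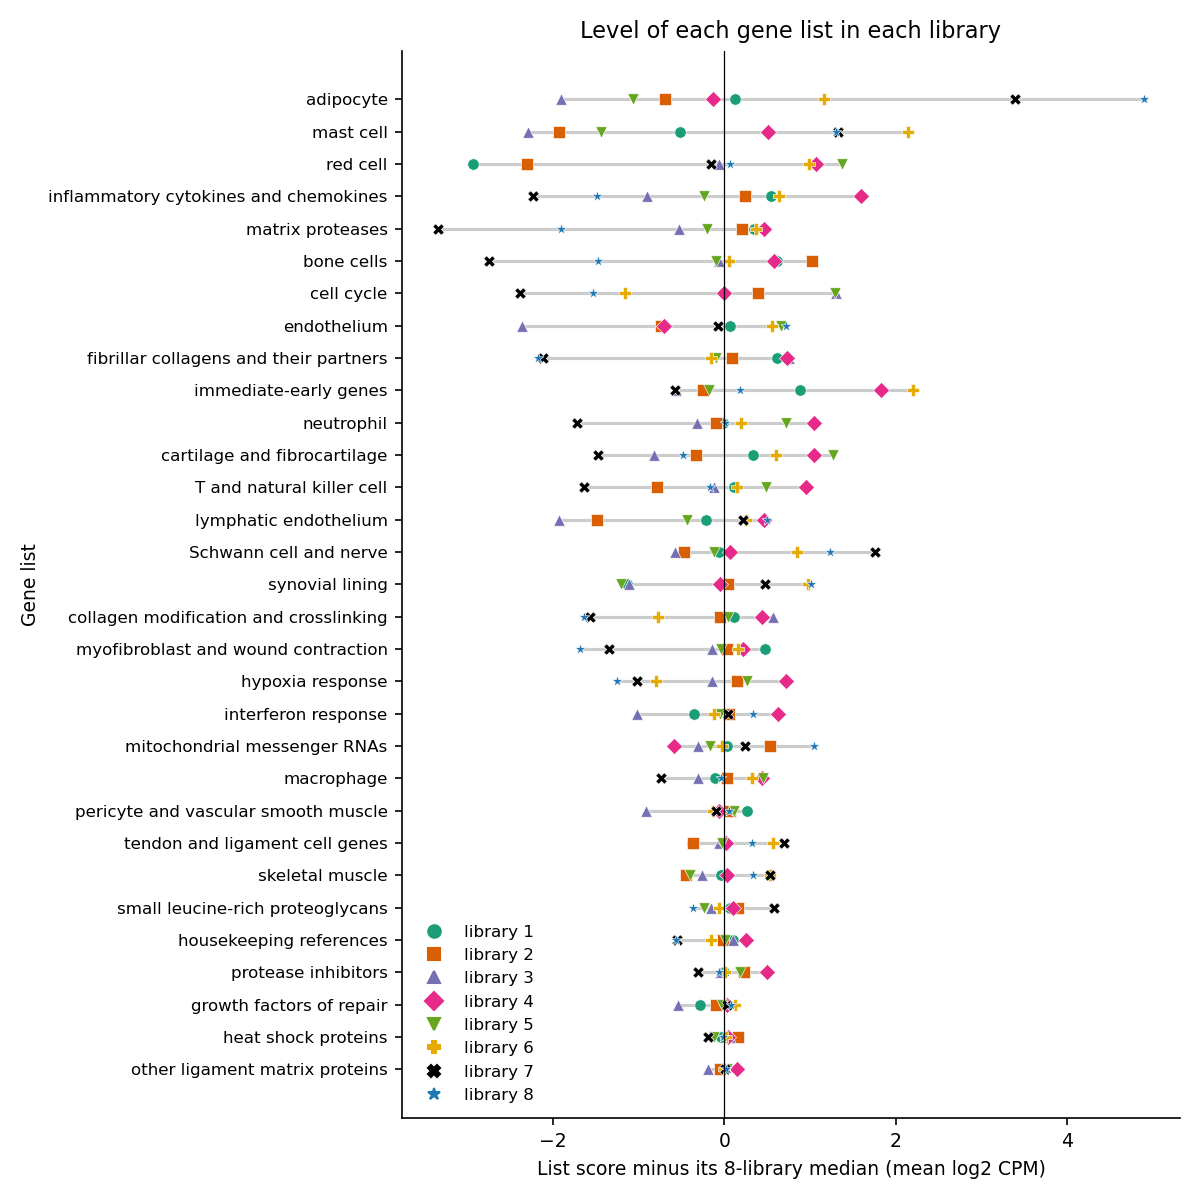
Level of each of 31 gene lists in each library, as the mean log2 CPM of its members minus the list's 8-library median, with 1 symbol per library and a grey line over the range. The adipocyte list ran from 0.52 to 7.33 log2 CPM, and the other ligament matrix proteins from 8.11 to 8.45.

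Of the 31 lists tested for spread, 23 were wider than random lists of like expression and 0 were narrower, with adjustment over the 31 lists. At an unadjusted p under 0.05 the macrophage list (p = 0.0474) was also wider, and again 0 were narrower. Of the 30 lists tested for shared movement, 21 had a higher mean correlation than random lists. The smallest p that 10000 random lists can give was 2e-04 for spread and 1e-04 for shared movement. Most lists were built around a cell type or a response, while random lists came from all 15133 genes. The number of wide lists may therefore reflect how the lists were chosen. Genes are not replicates, so these values describe these 8 libraries.

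**Figure D4:**
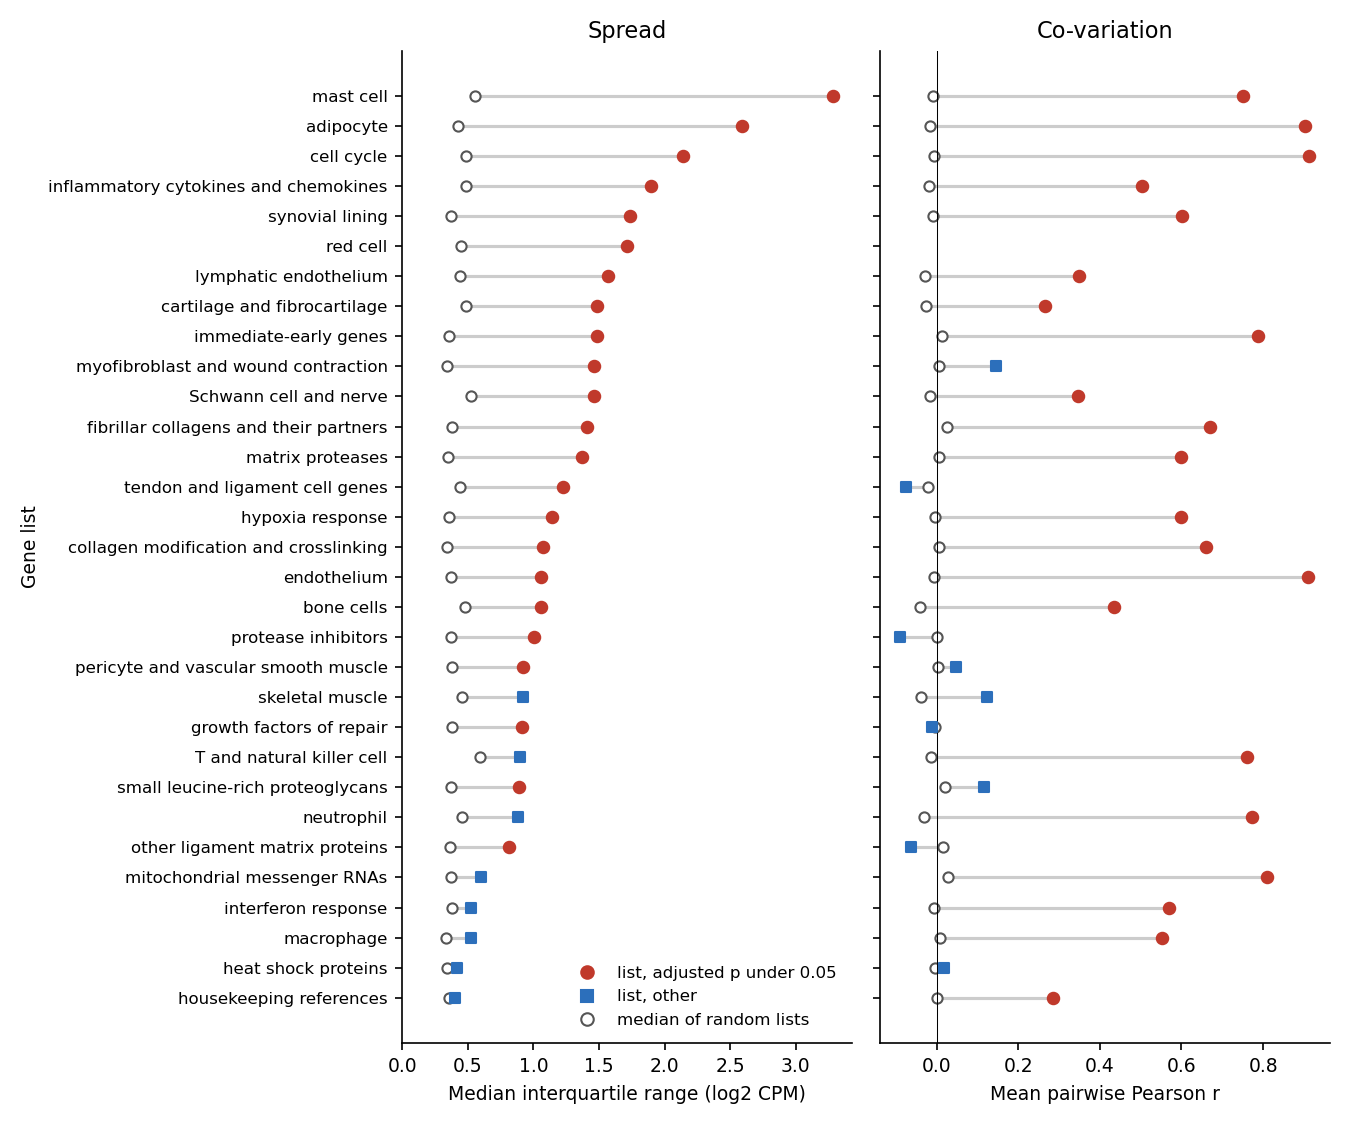
Median interquartile range of log2 CPM (left) and mean pairwise Pearson correlation (right) of each gene list over 8 libraries, as filled symbols, beside the median of 10000 random lists as open circles. Red circles mark adjusted p under 0.05, as for 23 of 31 lists on the left and 21 of 30 on the right.

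Of 9604 genes with a median of at least 5 CPM, the 20 with the widest interquartile range included genes of matrix breakdown, fat, mast cells and early response. MMP9 (5.36 on the log2 scale), the complement protein C7 (4.43), TPSAB1 (4.42), PLIN4 (4.07) and SPP1 (osteopontin, 4.03) led, followed by SFRP1, a secreted inhibitor of Wnt signalling (3.95). The remaining ones were APLN, PRND, MMP13, CXCL14, FABP4, CLIC5, NR4A1, SLC38A5, NR4A3, ANGPTL7, MAP1LC3C, COL11A1, ASPM and RELN. C7 ran from 0.279 CPM (2 counts) to 65.3 CPM, SPP1 from 0.671 to 278 CPM and SFRP1 from 0.978 to 273 CPM. The peptide hormone APLN had a median of 17.0 CPM (1.34 to 63.9) and the chemokine CXCL14 15.8 CPM (1.68 to 114). On GRCh38 MMP9 lies on chromosome 20 from 46008908 to 46016561, C7 on chromosome 5 from 40909252 to 40982939 and SPP1 on chromosome 4 from 87975650 to 87983426. The 10 narrowest genes were KIAA0930, EXD2, PHF20, PHACTR4, WIPI2, CBL, MBD1, TOM1L2, SOCS6 and SLTM. SLTM, which encodes an RNA-binding nuclear protein, stayed between 51.6 and 56.0 CPM, and WIPI2, which acts in autophagy, between 35.9 and 42.9 CPM. The median interquartile range of all 9604 genes was 0.36.

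Several familiar genes were listed at a count of 0 in every library. These were the cytokines TNF, CCL3, CCL4 and CCL5, the macrophage gene AIF1, the heat shock genes HSPA1A and HSPA1B, the early gene IER3, COL11A2, DERL3 and the globin gene HBM. Of these 11, the 10 other than HBM lie inside spans that alternate loci of the assembly repeat, so their levels are uncertain and a count of 0 does not show absence. B2M (median 8.96 CPM), TNXB, MYH11, MMP11 and OSCAR lie in such spans too and are uncertain in the same way.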

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

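Leaving out libraries 7 and 8 together was chosen after the results were seen, and the other settings were planned. With 1 CPM raised to 5 CPM, 8307 features were detected in every library and 12000 in at least 1. Between 10391 and 16959 features differed beyond counting error in the 6 other settings run, against 13715. Between 19 and 27 lists were wide, against 23, and 0 were narrower in any setting run. Shared movement was called for 18 to 22 lists, against 21, except for 13 when members needed a median of 5 CPM, where fewer members and lists could be tested. Of the 23 wide lists 19, and of the 21 lists with shared movement 17, kept their call in every planned setting in which they could be tested. The bone, red cell, cartilage and proteoglycan lists lost the call of spread in some setting, and the bone, cartilage, lymphatic and inflammatory lists that of shared movement. Macrophage, T cell, neutrophil, interferon and mitochondrial lists gained a call of spread in some. Without libraries 7 and 8, 23 lists were wide and 18 moved together.

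Correlated pairs of lists numbered 1 of 20, but 3 with DESeq2 size factors, 2 with members at a median of 5 CPM, 4 with the median of standardized members, 10 after adjustment for genes in no list, and 1 to 3 when each library was left out in turn. Of the 10, 6 were collagen pairs, which used 6 libraries before the adjustment and 8 after it, with none set apart by the cluster rule. The cause of the other shifts was not tested. Fewer pairs could be tested without some libraries, with 10 left without library 4 and 11 without library 3. The adjustment there ran over fewer pairs, so these counts do not compare directly with 1 of 20. Of the pairs with technical measures 1 passed, with 2 under plain CPM and 0 without mitochondrial and ribosomal RNA genes. That last setting removes every member of the mitochondrial messenger RNA list, so the pair that passed could not be tested there. The relation of matrix proteases with inflammatory genes was lost without library 7 (r = 0.82, exact permutation adjusted p = 0.132) and with members at a median of 5 CPM (r = 0.79, exact permutation adjusted p = 0.0642). Across the other settings run its adjusted exact permutation p was at most 0.0278. Of the 20 genes with the widest interquartile range, 10 were among the 20 widest by range and 20 were kept with DESeq2 size factors. Plain CPM moved the level of a library by -0.15 to 0.27 on the log2 scale, and DESeq2 size factors by -0.01 to 0.01. No paired analysis was possible because the labels give no groups and the library numbers pair nothing. Genes near the floor of 3 counts are limited by depth.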

Other observations

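All tests of explanations given here were chosen after the results were seen. The correlations between lists were planned, apart from keeping a cluster of libraries where scores split. Libraries 7 and 8 held little collagen and much fat cell transcript. They differed in small leucine-rich proteoglycans, whose list scored highest in library 7 (9.38) and lowest in library 8 (8.44). The collagen list scored 12.31, 11.79, 12.45, 12.42, 11.60, 11.54, 9.58 and 9.52 log2 CPM in libraries 1 to 8, with libraries 7 and 8 in a cluster of their own. The myofibroblast list parted in the same way, at 7.09, 6.64, 6.46, 6.83, 6.58, 6.77, 5.26 and 4.93. In library 8 the fat cell genes GPAM, PLIN4 and FABP4 reached 449, 304 and 287 CPM, and in library 7 they had 74.9, 121 and 257 CPM. The cell cycle list scored 2.66, 3.06, 3.96, 2.66, 3.95, 1.5, 0.28 and 1.12, so its lowest values were also in libraries 6, 7 and 8. The red cell list scored 0.56 and 1.18 in libraries 1 and 2, apart from 3.42, 4.56, 4.86, 4.48, 3.34 and 3.55 in libraries 3 to 8. On the first principal component, with 66.3% of the variance of the 500 most variable genes, libraries 1 to 8 lay at -17.7, -23.3, -33.3, -14.5, -16.7, 15.5, 47.1 and 42.8.

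Mast cell genes were high in libraries 6, 7 and 8 and also varied among the others, with scores of 1.24, -0.17, -0.53, 2.27, 0.32, 3.90, 3.08 and 3.06. Libraries 6, 7 and 8 also had the most features with a count, from 34280 to 35912, against 28647 to 30190 in the others. Whether library quality bears on these scores was not tested. Matrix proteases scored 7.00, 6.85, 6.12, 7.11, 6.44, 7.02, 3.30 and 4.74, and inflammatory cytokines and chemokines 3.65, 3.34, 2.20, 4.70, 2.86, 3.74, 0.87 and 1.61. These lists put the 8 libraries in the same order. Their Pearson correlation was 0.92 (exact permutation p = 2.48e-05, the smallest that the pairings of 8 libraries can give, adjusted p = 0.000496) and Spearman's rho was 1 (exact permutation p = 4.96e-05). Without the 2 libraries farthest from the median the correlation was 0.92, and 0.0106 of pairs of random lists were as strong. It did not pass without library 7 (r = 0.82, exact permutation adjusted p = 0.132) or with members at a median of 5 CPM (r = 0.79, exact permutation adjusted p = 0.0642).

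Of 20 pairs of lists, 6 had an unadjusted exact permutation p under 0.05 and 1 passed the adjusted threshold. Under the plan, pairs with the collagen, myofibroblast or red cell list would have had no correlation, so every adjusted p depends on including them. The 5 others are given here as values. Collagens and crosslinking genes had r = 0.82 over libraries 1 to 6 (exact permutation p = 0.00556, adjusted p = 0.0524) and rho = 0.94 (exact permutation p = 0.0167), with r = 0.85 without the 2 farthest, and over 6 libraries the pair also passed with DESeq2 size factors (adjusted exact permutation p = 0.0493), members at a median of 5 CPM (0.0444) and standardized members (0.0185). It also passed in 3 settings where the cluster rule no longer set libraries 7 and 8 apart, so that low-collagen libraries entered: without library 7, without library 8 and after adjustment for genes in no list. Macrophage and T cell lists had r = 0.85 (exact permutation p = 0.00786, adjusted p = 0.0524) and rho = 0.76 (exact permutation p = 0.0368), with r = 0.59 without the 2 farthest, and it passed in 5 of 17 other settings. Adipocyte and skeletal muscle lists had r = 0.78 (exact permutation p = 0.0200, adjusted p = 0.0998) and rho = 0.81 (exact permutation p = 0.0218), with r = 0.83 without the 2 farthest, and passed in 2 of 16 other settings. Red cell and neutrophil lists had r = 0.80 over libraries 3 to 8 (exact permutation p = 0.0278, adjusted p = 0.111) and rho = 0.94 (exact permutation p = 0.0167), with r = 0.81 without the 2 farthest, and passed in 0 of 13 other settings. These settings are not all alike, since in 5 of them all 8 libraries entered, with r from 0.29 to 0.59. Immediate-early and inflammatory lists had r = 0.75 (exact permutation p = 0.0335, adjusted p = 0.112) and rho = 0.81 (exact permutation p = 0.0218), with r = 0.56 without the 2 farthest, and passed in 2 of 18 other settings (r = 0.92, adjusted exact permutation p = 0.0131 with members at a median of 5 CPM).

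Of 93 pairs of a list with a technical measure, 8 had an unadjusted exact permutation p under 0.05. The 1 that passed was mitochondrial messenger RNAs with the mitochondrial share (r = 0.97, exact permutation adjusted p = 0.0277), which holds by construction (rho = 0.88, exact permutation p = 0.00724, and r = 0.90 without the 2 farthest). The 7 others are given as values. Against the mitochondrial share, housekeeping references had r = -0.86 (exact permutation p = 0.00404, adjusted p = 0.188), rho = -0.90 (exact permutation p = 0.00456) and r = -0.64 without the 2 farthest. Crosslinking genes had r = -0.82 (exact permutation p = 0.0113, adjusted p = 0.351), rho = -0.90 (exact permutation p = 0.00456) and r = -0.47 without the 2 farthest. Adipocyte genes had r = 0.78 (exact permutation p = 0.0202, adjusted p = 0.425), rho = 0.57 (exact permutation p = 0.151) and r = 0.03 without the 2 farthest, on which the relation rests. Hypoxia genes had r = -0.73 (exact permutation p = 0.0338, adjusted p = 0.524), rho = -0.69 (exact permutation p = 0.0694) and r = -0.26 without the 2 farthest. Against the library total, T and natural killer cell genes had r = -0.75 (exact permutation p = 0.0229, adjusted p = 0.425), rho = -0.71 (exact permutation p = 0.0576) and r = -0.70 without the 2 farthest. Cell cycle genes had r = -0.75 (exact permutation p = 0.0396, adjusted p = 0.526), rho = -0.74 (exact permutation p = 0.0458) and r = -0.58 without the 2 farthest. Mitochondrial messenger RNAs had r = 0.70 (exact permutation p = 0.0486, adjusted p = 0.532), rho = 0.81 (exact permutation p = 0.0218) and r = 0.90 without the 2 farthest.

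The low collagen transcripts of libraries 7 and 8 were weighed against admixed tissue and the mitochondrial share. No biological explanation was tested because the labels give no groups. Not weighed was the number of features with a count, 35055, 34280 and 35912 in libraries 6 to 8 against 28647 to 30190 in libraries 1 to 5. Library 6 had a collagen share of 9.48%. The 10 collagen genes lay at a median of -2.37 in library 7 and -2.46 in library 8 on the log2 scale, relative to their 8-library medians. Dilution by admixed tissue that lacks ligament matrix genes, as the only cause, would lower the 43 other ligament and crosslinking genes alike, but their median over both libraries was -0.29, with lower quartiles of -1.44 and -1.48, above the upper collagen quartiles of -2.0 and -2.01. Mitochondrial transcripts that take the counts would lower other genes by at most -0.39, and collagens still took 2.42% and 1.96% of the non-mitochondrial counts in libraries 7 and 8, against 12.0% to 22.2% in the others. Some members did go with the collagens, with a crosslinking median of -1.44 in library 7 and -1.59 in library 8 and SPARC at 1438 and 1676 CPM against a median of 6511, so dilution as part of the cause, or admixed tissue that itself makes ligament matrix, stays open as a candidate explanation.

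Immediate-early genes scored 7.29, 8.22 and 8.60 in libraries 1, 4 and 6, and 6.15, 5.84, 6.22, 5.82 and 6.58 in libraries 2, 3, 5, 7 and 8, and no biological explanation was tested. Library depth could not order these scores, since rho with the total was -0.19 (exact permutation p = 0.665), with 2 other libraries below and 3 above the total of the 3 highest. A general stress response during handling may also raise heat shock genes, but r between these lists was 0.21 (exact permutation p = 0.616), too imprecise over 8 libraries to decide, and HSPA1A and HSPA1B were listed at 0. Handling therefore stays open.

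Protein-coding genes listed at a count of 0 in all 8 libraries were concentrated where alternate loci repeat the assembly, and no biological explanation was tested. Inside these spans 399 of 724 genes (55.1%) had no count, against 781 of 18851 (4.14%) outside, an odds ratio of 28.4. Reads shared with copies on alternate loci, left uncounted as mapping to several places, are a candidate explanation for these genes. Proteasome subunit genes had no count for 2 of 2 genes inside the spans and 0 of 37 outside, and ribosomal protein genes for 1 of 3 inside and 0 of 77 outside. Whether the subunits inside the spans are made in every tissue was not checked. The levels of TNF, CCL3, CCL4, CCL5 and HSPA1A may therefore be missing from the counts rather than from the tissue.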
